A study of Homo sapiens with 9 samples.

How the data were processed

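The 9 arrays were Illumina HumanHT-12 v4 BeadChips hybridised with biotin-labelled RNA made from total RNA of BON-1 cells, in 1 colour, per the labels' protocols. The groups were taken from the sample titles as control vector, shRNA 1 and shRNA 2, with 3 arrays each. The labels speak of separately generated sets of cells and do not say how far these were separate cultures of one transduction, so p-values measure the spread between these samples.

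The main values were the deposited signal intensities of 47231 probes, neither background-subtracted nor normalized between arrays per the file headers and the values themselves. GenomeStudio is named in the submitters' processing notes, with no version. The same deposited table gives a detection p-value for each probe and array, in steps that correspond to 770 negative controls. The authors' value table holds linear intensity of 47219 of these probes. Its 9 columns have medians from 7.93 to 7.96 and a shared minimum of -23.85 and maximum of 26422, so it looks background-subtracted and quantile normalized, but the method is not given in the sources used here. Each of its columns had a rank correlation of 1 with the scanner signals of the array of the same name. It was used as an alternative, as log2 of the value, with values under 0 set to 0, plus 16.

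Background was corrected in limma 3.58.1 (R 4.3.3) with nec, which takes the negative control level from the detection p-values, with an offset of 16, followed by quantile normalization and log2. Fold changes of dim genes are understated on this scale. Probes with a detection p under 0.05 on at least 3 arrays were kept (22011). Probe names came from the platform annotation, in which 30108 probes had 1 gene symbol, 8 had several and 17115 were not listed. Of the named probes 30069 matched the RefSeq gene table (GRCh38.p14) by gene identifier and 0 symbols needed an update; no coordinates were used. The kept probes included 16744 with 1 gene and 5267 without a gene name. For the 3358 genes with more than 1 kept probe, the probe with the highest mean over all arrays was used. This left 12498 genes. All signal columns of the 9 arrays were used.

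Array precision is limited by the number of arrays. The median raw signal was between 119 and 129 on each array, and 41.4% to 44.9% of probes were detected.

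One linear model with a mean per group was fitted to all 9 arrays with lmFit and eBayes, and the contrasts were the mean of both shRNAs minus vector, each shRNA minus vector, and shRNA 2 minus shRNA 1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The lists, 18 of pathways and 3 of other cell types, were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists. Of the list members 665 were tested, 97 were too dim and 56 had no probe named for them. Genes were named by a rule: RABL6; the 10 genes in each direction with the largest smaller change of the 2 shRNAs, among those called with both and with all knockdown arrays on 1 side of all vector arrays; the 5 in each direction for each shRNA alone; the 8 in each direction between shRNAs; and up to 4 called members of each list plus up to 2 in the opposite direction. The groups, tests, lists, naming rule and the alternatives named below were fixed before the data were examined. The fit without the 2 shRNA arrays numbered 2, and all statements drawn from it, were added after the correlations between arrays were seen.

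The steps were tested on simulated data with the real gene means and spreads, 20 times, with 200 of 12498 genes changed. For both shRNAs against vector on 9 arrays, 51.1% of genes changed 2-fold and 89.3% of genes changed 4-fold were recovered, with a mean of 5.35 false calls. For shRNA 2 against shRNA 1 on 9 arrays 43.1% of 2-fold and 81% of 4-fold changes were recovered. The simulated shRNA groups held no array that resembled the other label, whereas each real one did. These shares therefore do not measure what the labelled comparison of the shRNAs could find. On 7 arrays 78.6% of 2-fold changes were recovered for both shRNAs and 58.3% between the shRNAs. The G1/S and DNA replication list, shifted by -0.50, was called in 20 of 20 simulations. The simulations took over the real gene means and spreads, not the correlation between genes. In the real data on 9 arrays the estimated correlation was 0.51 for this list and 0.80 for G2/M and mitosis. The 20 of 20 therefore does not show how far list calls hold for genes correlated to this degree. For the overlap of the 2 single comparisons, unchanged groups were simulated 100 times against a simulated vector group shared by both comparisons.

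The alternatives were no background correction, normexp with an offset of 50, median centring or cyclic loess in place of quantile normalization, the authors' value table, other filters on dim probes, other rules for probes of a gene, a trend or robust eBayes, array weights, only the compared groups in the fit, the replicate number as a block, a fold minimum of 1.5, an adjusted p under 0.01, other set tests, and each array left out. A BeadChip block was planned but the files name no chip.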

Results

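Gene expression was measured in BON-1, an established human cell line from a pancreatic neuroendocrine tumour, on 9 Illumina HumanHT-12 BeadChip arrays with 1 RNA sample each. The cells carried an empty control lentiviral vector or 1 of 2 short hairpin RNAs (shRNA 1 and shRNA 2) against RABL6A, a product of RABL6, the gene of a RAB-like GTPase. Each of the 3 groups held 3 arrays, numbered 1 to 3 in the labels, from cells that the labels describe as separately generated sets. The study asked what RABL6A contributes to passage from G1 into S phase and to proliferation of these tumour cells. Between 19565 and 21201 probes per array were detected above background, 12498 named genes were tested, and the number of arrays limits the precision.

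RABL6 itself was lower on every knockdown array than on every vector array. Its single probe (ILMN_1760628) read 7.57, 7.73 and 7.82 on the log2 scale with vector, 6.01, 5.99 and 5.22 with shRNA 1, and 5.67, 5.69 and 5.69 with shRNA 2. The group means were 7.71 ± 0.13 (SD, n = 3) with vector, 5.74 ± 0.45 (SD, n = 3) with shRNA 1 and 5.68 ± 0.01 (SD, n = 3) with shRNA 2. Averaged over both shRNAs, RABL6 fell by 1.99 on the log2 scale (SE 0.19, limma adjusted p = 0.0014), to 25.1% of the vector level. The raw knockdown signals, 130 to 171, lay near the median signals of the arrays, 119 to 129, though the probe was detected on each array. The 25.1% therefore depends on the background step and is not a measured residual level. The change was -1.02 with no background correction and -1.33 with normexp and an offset of 50. A two-sided exact permutation test of the 6 knockdown arrays against the 3 vector arrays gave p = 0.0119, the smallest that its 84 splits allow. The change was -1.97 (SE 0.21) with shRNA 1 and -2.02 (SE 0.21) with shRNA 2, and shRNA 2 minus shRNA 1 was -0.05 with a 95% interval from -0.54 to 0.44. Which transcript forms the probe reads was not examined.

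**Figure D1:**
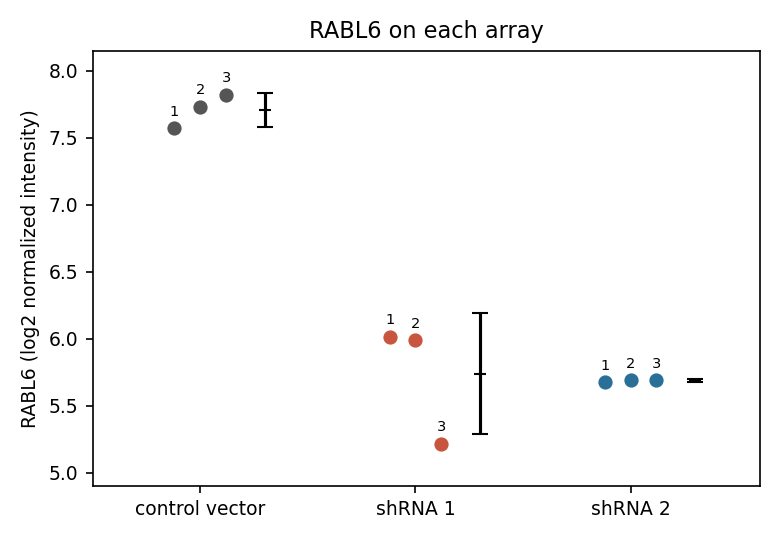
RABL6 on each array, as log2 normalized intensity on the y axis, with 1 point per array numbered by its replicate and the group mean and SD (n = 3) drawn beside the points. The 3 vector arrays lie between 7.57 and 7.82 and the 6 knockdown arrays between 5.22 and 6.01.

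The genome-wide profiles of the knockdown arrays did not group by shRNA. The array labelled shRNA 1 replicate 2 had a Pearson correlation across genes of 0.994 with shRNA 2 replicate 1 and 0.989 with shRNA 2 replicate 3, against 0.933 and 0.945 with shRNA 1 replicates 1 and 3. The array labelled shRNA 2 replicate 2 correlated at 0.995 with shRNA 1 replicate 1 and 0.989 with shRNA 1 replicate 3, against 0.933 and 0.939 with shRNA 2 replicates 1 and 3. Replicates 1 and 3 correlated at 0.988 within each shRNA, and the vector arrays at 0.995 in each pair. These correlations are across genes, which are not independent replicates. RABL6, at about the same level with both shRNAs, did not show which arrays carried which shRNA. All groups below follow the labels as given, and the totals of called genes, and the list members called with both shRNAs, are also given without the 2 shRNA arrays numbered 2 (7 arrays), a choice made after the correlations were seen that by itself narrows the spread within groups. If the 4 shRNA arrays kept were the ones with exchanged labels, their values for shRNA 1 and shRNA 2 would trade places.

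**Figure D2:**
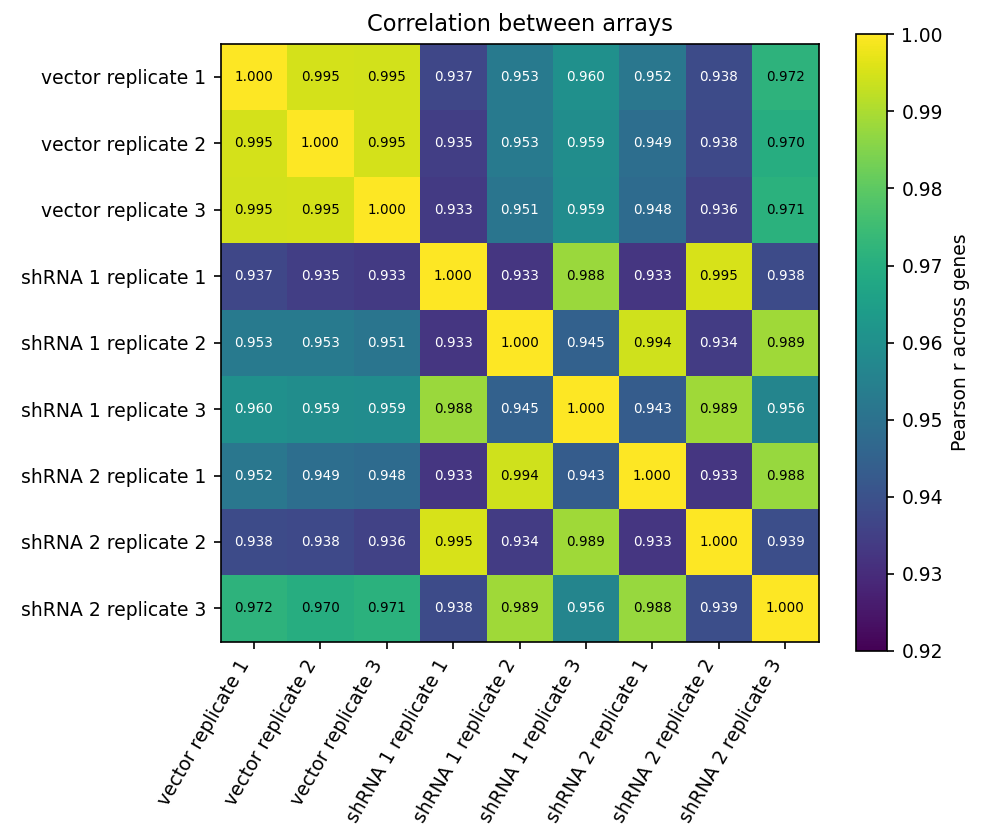
Pearson correlation across 12498 genes between each pair of the 9 arrays, named on both axes by group and replicate, with colour and number giving r. The vector arrays form 1 block, while shRNA 1 replicate 2 and shRNA 2 replicate 2 each show their highest values, 0.994 and 0.995, with an array labelled as the other shRNA.

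The first comparison set both shRNAs together against vector, the contrast that the study's design names. In cells with RABL6 shRNAs 38 of 65 tested genes of G1/S and DNA replication and 26 of 74 of G2/M and mitosis had less RNA. Camera called both lists at its preset correlation but not with an estimated one (adjusted p = 0.658 for each). CDC45, part of the helicase that unwinds DNA at replication forks, fell by 2.73 on the log2 scale (SE 0.51, 6 arrays against 3), and E2F2, a transcription factor of S-phase genes, fell by 2.16 (SE 0.29). TTR, the thyroid hormone carrier transthyretin, rose by 2.95 (SE 0.33), NT5E, the cell-surface enzyme that makes adenosine from AMP, by 2.77 (SE 0.43), and CCN2, a matrix-associated signalling protein, by 2.58 (SE 0.41). Also higher were HS6ST2, a heparan sulfate sulfotransferase, by 2.79, GHRL, the ghrelin precursor, by 2.55, SERPINF2, the plasmin inhibitor, by 2.48 (detected on 1 of 3 vector arrays, so its size is uncertain), SYT11, a synaptotagmin, by 2.32, C11orf54 by 2.32, PLCG2, a phospholipase C, by 2.30, and HTR3A, a serotonin-gated channel subunit, by 2.21. Also lower were CMTM7 at -2.80, C4orf46 at -2.53, CYB561A3 at -2.28, the acetylcholine receptor subunit CHRNA1 at -2.28 (detected on 3 of 6 knockdown arrays), the G protein subunit GNG4 at -2.26, SLC35A4 at -2.25, the transcription factor MYB at -2.14 and NKX2-2, a homeodomain factor of islet endocrine cells, at -2.09. The naming rule required each of these genes to have all 6 knockdown arrays on the same side of all 3 vector arrays, so that agreement is not a separate result.

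In total 2078 genes passed the limma test (adjusted p under 0.05) in this comparison, 1067 higher and 1011 lower than with vector. On 7 arrays 5151 passed (2590 higher, 2561 lower). These are 16.6% and 41.2% of the tested genes. Counts of called list members are to be read beside these shares and were not tested against them. The count of 2078 was 550, 489 and 509 without vector replicate 1, 2 and 3. Of the 20 genes above 3 lost their call without each of these arrays, 4 in all: HS6ST2, SYT11, CDC45 and MYB (highest adjusted p 0.0603). With arrays centred on their medians in place of quantile normalization, 613 genes were higher and 1432 lower, and the median change of all genes was -0.08 in place of 0.03.

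Among gene lists fixed before the data were examined, those of cell division fell. Of 65 tested genes of G1/S and DNA replication, 38 fell and 0 rose (53 fell when adjusted over the list alone), among them CDC45, E2F2, the DNA polymerase delta subunit POLD1 at -1.89 (SE 0.40) and UHRF1, which maintains DNA methylation at replication, at -1.87 (SE 0.42). The median of the list was -1.19, with a camera adjusted p of 1.68e-18 and an adjusted p = 0.658 with an estimated correlation. Of 74 genes of G2/M and mitosis, 26 fell and 0 rose (57 fell when adjusted over the list alone), with a median of -1.22. Examples were the kinesin KIF2C at -1.88 (SE 0.50), the spindle protein DLGAP5 at -1.82 (SE 0.41), the mitotic kinase AURKB at -1.81 (SE 0.43) and GTSE1 at -1.78 (SE 0.32). The camera adjusted p for G2/M was 1.68e-18, and the adjusted p = 0.658 with an estimated correlation; with the rotation test fry the adjusted p was 0.0209 for G1/S and 0.0507 for G2/M. On 7 arrays 53 G1/S and 59 G2/M genes fell and 0 rose. Averaged over the G1/S list, the arrays labelled shRNA 1 replicates 1, 2 and 3 lay at -1.65, -0.94 and -0.92 relative to vector, and those labelled shRNA 2 at -0.94, -1.57 and -0.51. For the G2/M list these means were -2.02, -0.95 and -0.85, and -1.03, -1.98 and -0.39. Of the 8 genes named from these 2 lists, 7, 7 and 6 lost their call without vector replicate 1, 2 and 3, and 1 each without shRNA 1 replicate 1 and shRNA 2 replicate 1 (adjusted p up to 0.13).

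The list of MYC targets and ribosome biogenesis genes, which also holds genes outside ribosome production, fell too. Of 47 MYC targets and ribosome biogenesis genes, 15 fell and 0 rose (21 fell and 2 rose when adjusted over the list alone), with a median of -0.42 and a camera adjusted p of 3.15e-08, or an adjusted p = 0.0467 with an estimated correlation (28 lower on 7 arrays, with an adjusted p = 0.243 with an estimated correlation). The spermidine synthase gene SRM was at -1.87 (SE 0.23), the folate carrier SLC19A1 at -1.13 (SE 0.13, detected on 2 of 6 knockdown arrays), the ribosome assembly factor RRS1 at -1.11 (SE 0.12) and MYC at -1.08 (SE 0.19). The list means per array were -0.56, -0.41 and -0.48 for shRNA 1 replicates 1, 2 and 3, and -0.41, -0.53 and -0.38 for shRNA 2. Of 40 ribosomal protein genes only RPS14 passed the test, at -0.50 (SE 0.12), and none did when adjusted over the list alone. The median of the ribosomal proteins was -0.16 (camera adjusted p = 0.0146, adjusted p = 0.782 with an estimated correlation). Of 38 oxidative phosphorylation genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), among them the cytochrome oxidase subunit COX7C by 0.56, the complex I subunit NDUFS3 by 0.52, and the succinate dehydrogenase subunits SDHA by 0.49 and SDHD by 0.48. The median was 0.19, with a camera adjusted p = 0.0146 and an adjusted p = 0.658 with an estimated correlation. The oxidative phosphorylation means per array were 0.27, -0.03 and 0.21 for shRNA 1 replicates 1, 2 and 3, and -0.04, 0.28 and -0.01 for shRNA 2. On 7 arrays the ribosomal protein list, with 5 lower, and the oxidative phosphorylation list, with 10 higher and 2 lower, were no longer called (adjusted p = 0.0984 and 0.056), nor was the ribosomal list with array weights (0.14) or fry (0.0685). Oxidative phosphorylation was not called with median centring (0.163) or without shRNA 2 replicate 2 (0.0678). Of the 9 genes named from these 3 lists, 6, 6 and 5 lost their call without vector replicate 1, 2 and 3, 2 without shRNA 1 replicate 1 and 1 without shRNA 2 replicate 1 (adjusted p up to 0.113).

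**Figure D3:**
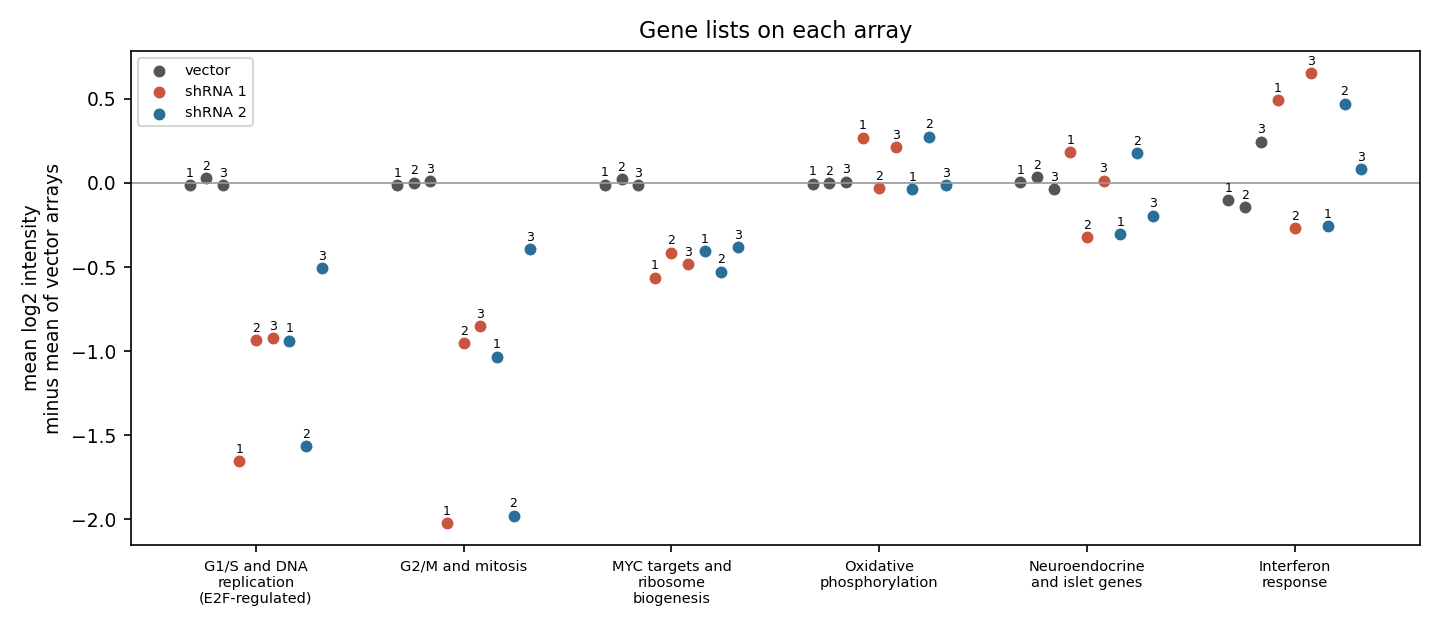
Mean log2 intensity of 6 gene lists on each array minus the mean of the vector arrays (y axis), with points coloured by group and numbered by replicate. The G1/S means of the knockdown arrays lie between -1.65 and -0.51, and the interferon and oxidative phosphorylation means separate shRNA 1 replicate 2 from replicates 1 and 3 of the same label.

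Regulators of the cell cycle and of cell survival moved in both directions. Of all tested genes 16.6% were called on 9 arrays and 41.2% on 7, and the counts of these lists were not tested against those shares. In the list of cell cycle inhibitors and pRB family genes, 1 of 21 rose and 4 fell (2 and 8 adjusted over the list alone). CDKN1B, the inhibitor p27, rose by 0.70 (SE 0.15), while the G1 kinase gene CDK6, at -0.999 (SE 0.14), the phosphatase gene CDKN3, at -0.95 (SE 0.27), and the pRB relative RBL1, at -0.81 (SE 0.19), fell, and the list as a whole was not called (camera adjusted p = 0.0598). Of 29 p53 targets, 4 rose and 2 fell (5 and 2 adjusted over the list alone), with SESN1 at 0.77, TP53I3 at 0.57, RRM2B at 0.54, AEN at -0.83 and XPC at -0.47 (camera adjusted p = 0.938). Of 31 apoptosis regulators, 4 rose and 1 fell (8 and 1 adjusted over the list alone). CASP2 fell by 1.60, while CASP9 rose by 0.83, MCL1 by 0.56 and XIAP by 0.54 (detected on fewer than 9 arrays). BIK, a BH3-only protein, was not detected on any vector array and was at least 2.08-fold higher with the shRNAs (camera adjusted p of the list 0.86). For such bounds the dim group was set to the lowest signal of a detected probe on each array. In the list of PNET tumour suppressors and PI3K-AKT-mTOR genes, 4 of 33 rose and 3 fell (4 and 3 adjusted over the list alone), with AKT1 at -1.61, EIF4EBP1 at -0.88, TSC1 at 1.02, VHL at 0.62 and the phosphatase subunits PPP2CB at 0.46 and PPP2R5A at 0.45 (camera adjusted p = 0.946). The list of cell cycle inhibitors and pRB family genes also holds kinase genes such as CDK6, so its fall is not one of inhibitors alone. It passed the threshold with no background correction (0.0465), normexp (0.0497), no filter on dim probes (0.0379), array weights (0.0452) or fry (0.0302), but not with an estimated correlation (adjusted p = 0.658). It also passed without vector replicate 2 (0.0457), shRNA 1 replicate 2 (0.033), shRNA 2 replicate 1 (0.0396) or shRNA 2 replicate 3 (0.0413). Of the 20 genes named from these lists, 12, 14 and 15 lost their call without vector replicate 1, 2 and 3, 7, 1 and 3 without shRNA 1 replicate 1, 2 and 3, and 7, 3 and 4 without shRNA 2 replicate 1, 2 and 3 (adjusted p up to 0.178). On 7 arrays 3 inhibitor and pRB family genes were higher and 11 lower, 8 and 5 p53 targets, 10 and 6 apoptosis regulators, and 6 and 8 of the PNET and PI3K-AKT-mTOR list.

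Endocrine genes were split, with counts to be read beside the 16.6% of all tested genes called (41.2% on 7 arrays). Of 32 neuroendocrine and islet genes, 3 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.444). NKX2-2, at -2.09, the vesicular monoamine transporter SLC18A1, at -2.06 (SE 0.18), and FEV, a transcription factor of serotonin-producing cells, at -1.26 (SE 0.22), fell, while the secretory chaperone gene SCG5 rose by 1.53 (SE 0.39), the somatostatin receptor SSTR2 by 1.08 (SE 0.21) and the enolase ENO2 by 0.62 (SE 0.16). Of 37 RAB GTPases and vesicle trafficking genes, 5 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.713), with RAB5B at -1.59, RAB22A at -1.54, RABEP1 at 0.74 and RAB21 at 0.70. The other 2 that fell, RABL2A and RABL2B, are near-identical copies whose probes may read both, and their values are uncertain (RABL2A at -0.56, but 0.13 with its probe of largest interquartile range). The means of the neuroendocrine list were 0.18, -0.32 and 0.01 for shRNA 1 replicates 1, 2 and 3, and -0.30, 0.18 and -0.20 for shRNA 2. Of the 12 genes named from these 2 lists, 9, 8 and 10 lost their call without vector replicate 1, 2 and 3, 6 and 4 without shRNA 1 replicate 1 and 3, and 3 and 2 without shRNA 2 replicate 1 and 3 (adjusted p up to 0.162). On 7 arrays 7 neuroendocrine genes were higher and 8 lower, and 8 and 10 vesicle trafficking genes.

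Metabolic, stress and matrix lists held single genes with large changes and were not called by camera on all 9 arrays. The hypoxia and glycolysis list was called by fry (0.0209) and by camera with no filter on dim probes (0.0448), the matrix list by fry (0.0272) and the interferon list by camera with array weights (0.0211). With an estimated correlation the adjusted p was 0.738 for hypoxia, 0.686 for matrix and 0.94 for interferon. Of 21 cholesterol biosynthesis genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.36), with DHCR7 at -1.88 (SE 0.16), TMEM97 at -1.41, MSMO1 at -0.96, SC5D at 0.76 and PMVK at 0.69. Of 42 unfolded protein and ATF4 response genes, 4 rose and 7 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.246), with the amino acid transporter SLC7A5 at -1.56 (SE 0.12), PDIA4 at -0.99, SEL1L at 1.11, VLDLR at 0.90, NUPR1 at 0.72 and CEBPG at 0.53. Of 31 hypoxia and glycolysis genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.156), with INSIG2 at 1.36, ANGPTL4 at 1.28, BNIP3 at 0.66 and PFKFB3 at -0.62. Of 28 matrix and epithelial-mesenchymal genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.212), with CCN2, TAGLN at 0.94, KRT8 at 0.85 and ITGA6 at 0.80. Of 24 secretory and inflammatory genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.938), with the collagenase MMP1 at 1.51, MMP10 at 1.80, NFKBIE at 0.64 and NFKB1 at -0.84. Of 39 interferon response genes, OAS3 fell by 1.38 and PARP9 rose by 0.50, and 0 passed when adjusted over the list alone (camera adjusted p = 0.212, and 0.0289 without vector replicate 3 or 0.0277 without shRNA 1 replicate 2). The interferon means per array were 0.49, -0.27 and 0.65 for shRNA 1 replicates 1, 2 and 3, -0.26, 0.47 and 0.08 for shRNA 2, and -0.10, -0.14 and 0.25 for vector. Of 15 replication-dependent histone genes only H3C10 passed, at 0.73, a value that is uncertain because histone genes have near-identical copies (0 adjusted over the list alone; camera adjusted p = 0.906). Of the 26 genes named from these lists, 16, 17 and 17 lost their call without vector replicate 1, 2 and 3, 10, 1 and 6 without shRNA 1 replicate 1, 2 and 3, and 10, 1 and 2 without shRNA 2 replicate 1, 2 and 3 (adjusted p up to 0.197). On 7 arrays 3 cholesterol genes were higher and 7 lower, 9 and 13 unfolded protein and ATF4 genes, 12 and 3 hypoxia genes, 10 and 5 matrix genes, 3 and 6 secretory genes, 13 and 1 interferon genes, and 5 and 2 histone genes.

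No list of markers of other cell types was called by camera on all 9 arrays. Of 6 leukocyte markers tested, LCP1 rose by 1.53 (SE 0.21) and HLA-DRA by 1.21 (SE 0.19), 2 also when adjusted over the list alone (camera adjusted p = 0.265). None of 3 fibroblast markers (camera adjusted p = 0.742) and none of 9 exocrine pancreas markers (0.938) passed over all genes, and over the list alone 0 fibroblast markers passed while 1 exocrine marker was higher and 1 lower. The rotation test fry called the leukocyte markers with both shRNAs (adjusted p = 0.00671), shRNA 1 (0.0156) and shRNA 2 (0.0139), while camera with an estimated correlation gave an adjusted p of 0.658, 0.695 and 0.671. Their means per array were 0.38, 0.63 and 0.48 for shRNA 1 replicates 1, 2 and 3, 0.81, 0.35 and 0.57 for shRNA 2, and 0.04, -0.09 and 0.05 for vector. The fibroblast means were 1.20, -0.39 and 0.94 for shRNA 1, and -0.18, 1.03 and -0.25 for shRNA 2. On 7 arrays 3 leukocyte markers were higher and 0 lower, 1 and 0 fibroblast markers, and 1 and 2 exocrine markers. Of the 97 genes named for this comparison, 35 kept their call in each fit without 1 array. All 97 were called on 7 arrays, but so were all 2078 genes called on 9 arrays. The 7-array calls thus say nothing particular about the named genes.

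Each shRNA was then set against vector on its own. With shRNA 1, TTR rose by 3.02 (SE 0.38), SMLR1 by 2.91, NT5E by 2.72, HS6ST2 by 2.62 and ABAT, the enzyme that degrades GABA, by 2.60. The largest decreases under the naming rule were CMTM7 at -3.11, CDC45 at -2.95, C4orf46 at -2.64, CYB561A3 at -2.41 and SLC35A4 at -2.36. In all 1395 genes changed, 700 higher and 695 lower (370 and 930 with median centring), and 5486 on 7 arrays. Of the G1/S list 29 genes fell (53 over the list alone; median -1.24; camera adjusted p = 5.76e-19, adjusted p = 0.695 with an estimated correlation). Of the G2/M list 16 fell (42 over the list alone; median -1.26; 8.80e-19, adjusted p = 0.695 with an estimated correlation), and of MYC and ribosome biogenesis 13 (20 over the list alone; median -0.39; 1.59e-08, adjusted p = 0.0424 with an estimated correlation). Of oxidative phosphorylation 4 rose (5 over the list alone; median 0.21; 0.0115, adjusted p = 0.695 with an estimated correlation; 0.105 with median centring). The list of cell cycle inhibitors and pRB family genes had 1 higher and 2 lower (1 and 3 over the list alone, median -0.41). Its camera adjusted p was 0.029, and the adjusted p = 0.695 with an estimated correlation. The call was lost without shRNA 1 replicate 1 (0.0667) or 3 (0.0615). The ribosomal proteins had 0 called members (median -0.15; 0.029, adjusted p = 0.806 with an estimated correlation), with the list call lost without shRNA 1 replicate 1 (0.0624) or 2 (0.2), with array weights (0.367) and on 7 arrays (0.27). The interferon list was called without vector replicate 3 (0.0102) or shRNA 1 replicate 2 (0.00136), with array weights (0.000346) and on 7 arrays (0.000779). It was not called with an estimated correlation (adjusted p = 0.944 on 9 arrays and 0.749 on 7). With fry the G2/M (0.0704) and ribosomal protein (0.14) lists were not called. The unfolded protein and ATF4 (0.049), hypoxia and glycolysis (0.0406) and matrix (0.0489) lists were, each with an adjusted p = 0.72 with an estimated correlation. The count of genes was 154, 138 and 147 without vector replicate 1, 2 and 3, 274 without shRNA 1 replicate 1, 818 without shRNA 1 replicate 3, and 2153 without shRNA 2 replicate 2, which enters through the shared spread. Of the 10 genes above 7 lost their call without each vector array, 5 without shRNA 1 replicate 1, 2 without shRNA 1 replicate 3 and 1 without shRNA 2 replicate 1.

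With shRNA 2, PLGLB1 rose by 3.61, VTN, the adhesion protein vitronectin, by 2.97, HS6ST2 by 2.96, TTR by 2.87 and NT5E by 2.82. PLGLB1 has a near-identical copy, so its value is uncertain, and VTN was detected on 1 of 3 vector arrays, so its size is uncertain too. Lower were CDC45 at -2.50, CMTM7 at -2.49, C4orf46 at -2.41, GNG4 at -2.37 and CHRNA1 at -2.35. In all 1081 genes changed, 573 higher and 508 lower (314 and 812 with median centring), and 4418 on 7 arrays. Of the G1/S list 15 genes fell (39 over the list alone; median -1.08; camera adjusted p = 8.38e-17, adjusted p = 0.671 with an estimated correlation). Of the G2/M list 9 fell (21 over the list alone; median -1.11; 8.38e-17, adjusted p = 0.671 with an estimated correlation), and of MYC and ribosome biogenesis 11 (16 over the list alone; median -0.42; 1.55e-07, adjusted p = 0.059 with an estimated correlation). The ribosomal proteins had 1 lower (0 over the list alone; median -0.14; 0.014, adjusted p = 0.765 with an estimated correlation), with the list call lost without shRNA 2 replicate 1 (0.0598) or 2 (0.0566), with array weights (0.102), on 7 arrays (0.0937) and with fry (0.103). Of oxidative phosphorylation 3 rose (2 over the list alone; median 0.13; 0.0429, adjusted p = 0.671 with an estimated correlation). This list call was lost without vector replicate 1 (0.0716) or 2 (0.0643), shRNA 1 replicate 1 (0.0523) or 2 (0.0667), or shRNA 2 replicate 2 (0.262), and with median centring its median was -0.0075 (0.225). It was also lost on 7 arrays (0.393), with array weights (0.232), cyclic loess (0.0517), detection on all 9 arrays (0.0752), only the compared groups (0.0722) and fry (0.0743). The G2/M call was lost with fry (0.103). Without shRNA 2 replicate 2 the histones (0.0343), cholesterol biosynthesis (0.0343) and hypoxia and glycolysis (0.0445) were called. The hypoxia list was also called with no filter on dim probes (0.0313), the probe of largest interquartile range (0.0357) and fry (0.0474). Cholesterol was called with array weights (0.0499) and on 7 arrays (0.0382), and the histones on 7 arrays (0.00906). With an estimated correlation the adjusted p was 0.671 for hypoxia, 0.81 for cholesterol and 0.948 for histones on 9 arrays, and 0.537 for each of the 3 on 7 arrays. The count of genes was 119, 118 and 126 without vector replicate 1, 2 and 3 and 184 without shRNA 2 replicate 1. Of the 10 genes above 7 lost their call without each vector array and without shRNA 2 replicate 1, 2 without shRNA 2 replicate 3, and 2 and 3 without shRNA 1 replicate 1 and 3.

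The overlap of the 2 single comparisons was then counted. Both tests were passed with the same sign by 933 genes, 482 higher and 451 lower, and with opposite signs by 0, while 462 passed with shRNA 1 alone and 148 with shRNA 2 alone. With median centring 946 genes went the same way, 267 higher and 679 lower. Each label group held an array that resembled the other label, which draws the 2 group means together. Among them were TTR, NT5E and GHRL on the higher side and CDC45, E2F2 and MYB on the lower. Independent lists of these sizes would share 32.1 higher and 28.2 lower genes. Simulated unchanged groups, set against a simulated vector group shared by both, shared 0. Groups without any change give almost no calls, so this 0 was fixed in advance. The simulation also held no correlation between genes and no array that resembled the other label. Its values therefore do not measure what the overlap owes to the shRNAs. The log2 fold changes of the 2 shRNAs correlated across genes at r = 0.909 (simulated 0.105), with a covariance of 0.287 (simulated 0.00886). The 3 vector arrays are too few to split, so part of this overlap can come from the shared controls. On 7 arrays 1916 genes went the same way and 506 opposite ways, with r = 0.384 (simulated 0.217) and a covariance of 0.155 (simulated 0.00843). The count of 933 was 106, 104 and 110 without vector replicate 1, 2 and 3, 272 without shRNA 1 replicate 1 and 183 without shRNA 2 replicate 1, and r was 0.732 without shRNA 1 replicate 2 and 0.666 without shRNA 2 replicate 2.

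**Figure D4:**
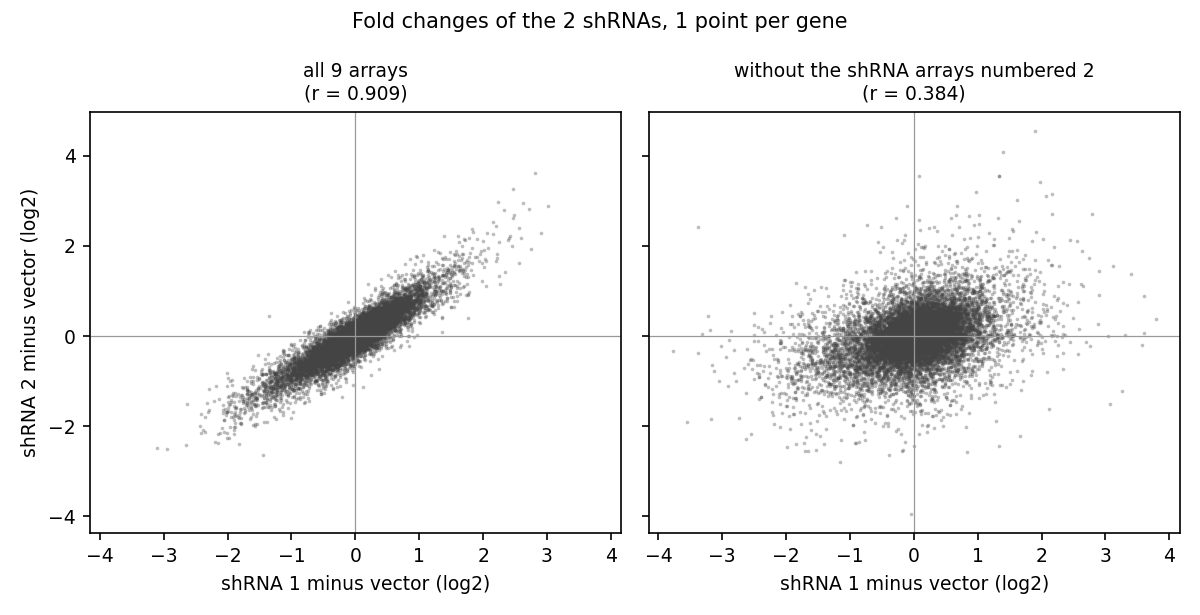
Log2 fold change against vector of shRNA 2 (y axis) against that of shRNA 1 (x axis), 1 point per gene, for all 9 arrays and without the shRNA arrays numbered 2. The points lie along the diagonal with all 9 arrays (r = 0.909) and spread widely with 7 arrays (r = 0.384).

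The direct comparison of shRNA 2 with shRNA 1 called 0 genes in limma, with 96 of 12498 at an unadjusted p under 0.05. That is a smaller share than the 0.05 that unchanged genes would give on average, so the 96 are no sign of a difference. Each label group held an array that resembled the other label, which can hide differences, so the 0 does not show that the shRNAs act alike. The split that exchanges the 2 arrays numbered 2 called 6707 genes. TTR and NT5E, which were named because both shRNAs changed them, were 10.94 and 10.07 on the log2 scale with shRNA 1 and 10.79 and 10.17 with shRNA 2. Camera called 3 lists, G1/S (median 0.13, adjusted p = 0.0223), interferon (-0.16, 0.0223) and cholesterol biosynthesis (-0.15, 0.00254), each with an adjusted p = 0.895 with an estimated correlation and 0 called members. On 7 arrays the same test called 5152 genes, 2416 higher and 2736 lower with shRNA 2. A large count follows in part from leaving out the arrays that resembled the other label. Array weights on all 9 arrays gave 4345.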

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

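The tests of the correlations between arrays, of the arrays numbered 3 and of the difference between the shRNAs on 7 arrays were chosen after those results were seen; the counts over other splits of the samples were planned before.

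Both shRNA arrays numbered 2 stood with the arrays labelled as the other shRNA. An exchange of labels between the shRNA groups is a candidate explanation: each of these arrays correlated better with replicates 1 and 3 of the other label than with those of its own, by at least 0.0437, and the 2 arrays are each out of place in the opposite group. The data do not show whether the arrays numbered 2 or the other 4 would be exchanged, nor at which step. A batch shared by the arrays numbered 2 is argued against by their correlation with each other, 0.934, and poor array quality by their best correlations, of which the lower was 0.994. Cell states unrelated to the shRNA stay open, since RABL6 differed by only -0.053 between the labels and cannot place the arrays.

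The shRNA arrays numbered 3 lay closer to vector than those numbered 1, with Pearson correlations with vector replicate 1 of 0.96 against 0.937 for shRNA 1 and 0.972 against 0.952 for shRNA 2. Vector cells mixed into these cultures are argued against by RABL6: the shrinkage of all genes would need a rise of 0.72 with shRNA 1 and 1.05 with shRNA 2, and the observed changes were -0.80 and 0.02, short by at least 3.95 residual SDs of 1 array. A difference between 2 arrays has a larger SD, so the gap is smaller on that scale. The implied rises are approximate, since they rest on a slope on the log2 scale. A compression of intensities that keeps the order of genes would leave rank correlations with vector alone, and these differed by at least 0.0201. Quantile normalization had already removed such a compression before both kinds of correlation, so this is not a separate test. A shorter time since transduction, or another difference between the separately generated sets, stays open and was not tested.

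On 7 arrays limma called 5152 genes between shRNA 2 and shRNA 1 in a direct test, although the test on 9 arrays called 0. The 2 arrays were left out because they resembled the other label, which sets the remaining pairs apart, so the size of this count does not show that the shRNAs differ. A different depth of knockdown as the whole cause is argued against by direction. Of the genes called with both shRNAs against vector on 7 arrays, 20.9% went opposite ways. RABL6 differed by 0.07 (95% interval -0.47 to 0.60). Its knockdown signals lay near background, so this value cannot exclude a different depth. A culture or array batch that follows the shRNA cannot be told apart from the shRNAs for these 5152 genes, because no label or file gives a batch. Effects of the hairpins on other transcripts were not tested, since their sequences were not used here.

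Probes without a gene name, which no comparison of the report uses, also carried signal: 325 of 5267 passed the limma test for both shRNAs against vector, 127 higher and 198 lower, with log2 changes from -2.08 to 2.74. On 7 arrays 730 passed.

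Other splits of the samples were counted for each comparison. For both shRNAs against vector, 7 of 100 drawn splits of the 9 arrays into 3 groups of 3, of 840 in all, called at least as many genes as the real 2078, with 6155 the highest of the others. For genes changed the same way, 7 of 100 reached the real 933, with 3004 the highest other. Of these 7 splits, 3 (the real one and 2 more) keep the vector arrays as the control side and so hold the same contrast; without the 2, 5 of 98 splits reached the real count for each result, the real one included, a share of 0.051. Chance is not excluded by these counts. The splits with several times the real count point to a structure of the samples: the 6155 genes came from the split that set shRNA 1 replicate 2 with shRNA 2 replicates 1 and 3, and shRNA 1 replicates 1 and 3 with shRNA 2 replicate 2. For gene lists called with both shRNAs, 40 of 100 splits reached the real 5, with 8 the highest other, and chance is not excluded. The single comparisons have 10 splits of 6 arrays, too few for a share under 0.05. For shRNA 1 against vector, 1 of 10 reached the real 1395 genes (highest other 0) and 4 the real 6 lists (highest other 9). For shRNA 2, 1 of 10 reached 1081 genes (highest other 0) and 5 the real 5 lists (highest other 7). Between the shRNAs all 10 reached the real 0, and the highest other, 6707, came from the split that exchanges the 2 arrays numbered 2, with 0 for each of the remaining splits.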

How the results depend on the processing

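The fit without the shRNA arrays numbered 2 was chosen after seeing the data; the other alternatives were planned. RABL6 stayed called in each one run, from -2.17 to -1.02 on the log2 scale, and -2.06 to -1.86 without 1 array. The cause of the changes below was not tested unless the setting itself removes arrays. Array weights gave 5588 genes for both shRNAs, 6186 for shRNA 1, 4041 for shRNA 2, 4345 between shRNAs, 2276 changed the same way, and r = 0.462; the weights of the 2 shRNA arrays numbered 2 were the lowest, 0.149 and 0.147. On 7 arrays the values were 5151, 5486, 4418, 5152, 1916 and r = 0.384, with 3 lists for both shRNAs. An adjusted p under 0.01 gave 554, 180 and 146 genes, 130 the same way, and 3 lists in each comparison. Camera with an estimated correlation called 1 list for both shRNAs, 1 for shRNA 1 and 0 for shRNA 2. Without 1 array the counts ran from 489 to 2583 for both shRNAs, 138 to 2153 for shRNA 1, 118 to 1599 for shRNA 2, 0 to 0 between shRNAs, 104 to 999 the same way, r from 0.666 to 0.957, and lists from 4 to 7, 4 to 7 and 4 to 6. RABL2A reversed, to 0.13, with the probe of largest interquartile range.

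Whether replicate numbers pair the arrays is not settled. Deviations from the group means of same-numbered vector and shRNA 1 arrays correlated at 0.0842, 0.028 and 0.0879, and vector and shRNA 2 at 0.0969, 0.0666 and 0.153. Differently numbered vector and shRNA arrays correlated at -0.08 to -0.0058. Same-numbered arrays of the 2 shRNAs correlated at -0.71, -0.89 and -0.24. These last values cannot test pairing, because each label group held an array that resembled the other label. Each vector array correlated best with its own number, a hint from the data and not the design. With the replicate block 1106 genes were called for both shRNAs, 449 for shRNA 1, 282 for shRNA 2 and 260 the same way.

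Other settings kept total counts within 1.5 times, 1608 to 2195 for both shRNAs, but median centring moved the balance: 613 higher in place of 1067 for both shRNAs, 370 in place of 700 for shRNA 1, 314 in place of 573 for shRNA 2 and 267 in place of 482 the same way. The 143 named-gene results were each counted once per setting. Without 1 array 366 of these values lost their call and 921 stayed the same. Under other settings 230 lost it, 2234 stayed the same and 1 reversed. Dim signal limits 97 list members. The BeadChip block was not run.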

Other observations

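All values in this part come from the 7 arrays without the shRNA arrays numbered 2 (2 arrays per shRNA, 3 vector arrays), a fit chosen after seeing the data, with genes named by the rule fixed for the comparison of the shRNAs. The 2 arrays were left out because they resembled the other label, so the p-values describe the 4 kept arrays and do not show that the shRNAs differ. All shRNA names are as labelled. If the 4 kept arrays were the ones with exchanged labels, which the data do not show, each value given here for shRNA 1 would belong to shRNA 2 and the reverse, and each difference would change sign (DKK1 -5.80 and VSTM2L 4.58).

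DKK1, a secreted inhibitor of Wnt signalling, was 5.80 higher on the log2 scale on the arrays labelled shRNA 2 than on those labelled shRNA 1 (SE 0.22), at -3.37 against vector with shRNA 1 and 2.42 with shRNA 2. CCN1, a matrix-associated relative of CCN2, was 3.47 higher with shRNA 2, and was 0.09 against vector with shRNA 1 and 3.56 with shRNA 2. The small GTPase RAC1 (3.68 higher with shRNA 2), TXNDC12 (3.44), TNFRSF21 (3.34), S100A16 (3.33), TNFRSF12A (3.33) and COLEC12 (3.20) followed. RAC1 was -3.23 against vector with shRNA 1 and 0.44 with shRNA 2, and TNFRSF21 -3.31 and 0.04. Lower with shRNA 2 than with shRNA 1 were VSTM2L at -4.58, NELL1 at -4.48, the cytochrome oxidase subunit COX6A1 at -3.89, HEPACAM2 at -3.87, AUH at -3.77, TGM3 at -3.76, KCNMB2 at -3.74 and PLA2G10 at -3.53. COX6A1 was -0.05 against vector with shRNA 1 and -3.94 with shRNA 2.

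Camera at its preset correlation also called lists between the shRNAs on these arrays. By the labels, of 39 interferon response genes, 16 rose and 1 fell with shRNA 1 (camera adjusted p = 0.000779, adjusted p = 0.749 with an estimated correlation), while 3 rose and 5 fell with shRNA 2 (camera adjusted p = 0.891), and the difference was called (0.00101, adjusted p = 0.567 with an estimated correlation). Of 15 histone genes, 9 rose and 0 fell with shRNA 2 (camera adjusted p = 0.00906, adjusted p = 0.537 with an estimated correlation), and 0 rose and 4 fell with shRNA 1 (camera adjusted p = 0.184). Of 21 cholesterol biosynthesis genes, 9 fell and 2 rose with shRNA 2 (camera adjusted p = 0.0382, adjusted p = 0.537 with an estimated correlation). Of 74 G2/M genes, 66 fell with shRNA 1 (median -1.43, camera adjusted p = 3.03e-15, adjusted p = 0.749 with an estimated correlation) and 19 with shRNA 2 (median -0.68, camera adjusted p = 2.33e-06, adjusted p = 0.622 with an estimated correlation, and 0.2 with fry). The difference in G2/M was called (camera adjusted p = 0.000103, adjusted p = 0.621 with an estimated correlation). So were those in G1/S (0.000641, adjusted p = 0.621 with an estimated correlation), histones (0.000539, adjusted p = 0.481 with an estimated correlation) and cholesterol biosynthesis (0.00636, adjusted p = 0.481 with an estimated correlation). All 3 fibroblast markers tested were lower with shRNA 2 than with shRNA 1 (camera adjusted p = 0.0297, adjusted p = 0.481 with an estimated correlation), and all 3 rose with shRNA 1 against vector (camera adjusted p = 0.059).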
